A study of Homo sapiens with 4 samples.

How the data were processed

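Total RNA from 4 samples of A375 cells, 2 control and 2 treated with ADI, was made into libraries with a stranded poly(A) mRNA kit and adapters that carry molecular identifiers, and was sequenced as read pairs, per the labels' protocols. The samples were assigned to control or ADI by the treatment given in their labels. The authors deposited raw read counts per gene for every library in 1 table, with versioned Ensembl gene identifiers, coordinates and exonic gene length. Per the submitters' processing notes, STAR 2.7.11b, featureCounts 2.0.1 and genome build hg38 were used. The annotation release, the strand setting, the use of the molecular identifiers and the treatment of reads that map to several places are not given in the sources used here.

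The table held 78724 genes, of which 38464 had at least 1 count. Gene symbols were taken from a reference table matched on the identifier (61481 matched), and biotypes from the GENCODE 29 annotation or, where it had none, from a RefSeq gene table (57302 matched, 19830 of them protein-coding). Genes without a symbol held at most 0.233% of a library's counts, and no row lacked a gene. Total counts were 19545694 and 19979467 (control) and 16521311 and 15848802 (ADI). A gene with 0 counts in a library can lie up to 3 counts, or 0.1502 to 0.1893 CPM, above 0. For a gene at 0 in both libraries of a group, the fold is given as a lower bound against 3 counts per library. For a group with 1 to 3 counts in all, a scaled ratio is given with its exact conditional binomial 95% interval. It is the ratio of summed counts after each sum is divided by the summed TMM-scaled library sizes of its group. Such intervals and floors cover counting error only, since reads that were not collapsed by identifier are not independent molecules.

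The 2 libraries of a group were compared with each other before they were averaged. The chi-square per degree of freedom was 2.02 over 15854 genes for the controls and 9.00 over 15830 genes for the ADI pair, so both pairs differed by more than sampling noise and all 4 libraries were kept. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.998 and 0.991.

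The deposited counts were compared with gene overlaps. Of 302 protein-coding genes without an exonic base of their own on their strand, by the exon coordinates deposited with the counts, 94.0% had fewer than 4 counts in all. Of 26 that were free of other genes on their own strand but had under 10% free bases when both strands were considered, 76.9% had fewer than 4 counts, against 24.1% of the genes with at least 90% free bases. Values of genes that overlap others on either strand, antisense genes included, are therefore uncertain. Among the 87 genes given by the rule, 2 had under 50% free bases (SARS2 and EBP).

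Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), using filterByExpr at its defaults (minimum count 10, minimum total 15), TMM scaling, a robust quasi-likelihood fit on treatment and a two-sided quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Of the 78724 genes, 16962 were tested. The biological coefficient of variation was 0.0697. CPM values use TMM-scaled library sizes.

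The 35 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list and with fry. The genes named were set by a rule before the data were examined. They are ASS1, ASL, SLC7A1, ATF4, DDIT3 and ASNS, then the 8 largest rises and 8 largest falls among protein-coding genes with at least 5 CPM in the higher group and no overlap between groups, and then the 2 members of each list with the largest change among those called with at least 1 CPM in the higher group. The rule gave 87 genes, of which 1 is not reported here. A further 43 genes were named after their values were seen, which is said where they appear, and so were the low markers given as counts.

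The test was tried on simulated counts for 15737 genes, drawn from the means of the control libraries and the library sizes of all samples. Each gene had the same spread in both groups, so the larger spread of the ADI pair was not simulated. It recovered 49.2% of 61 genes changed 1.5-fold, 79.0% of 62 changed 2-fold and 92.1% of 63 changed 4-fold, and 20 of its calls (12.7%) were false, above the nominal level. So few changed genes were simulated that this share does not carry over to data in which 70.2% of genes were called, a case that was not simulated.

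The alternatives were RLE (the size factors of DESeq2), upper-quartile scaling, library totals, no filter, a stricter filter (50 counts in 2 libraries), DESeq2 1.42.0, limma-voom, a replicate block, a test against a 1.2-fold change, protein-coding genes alone, leaving out each library in turn, and for the lists also genes of several lists kept in the first alone. A crossed pairing, thinning to the smallest library and leaving out the mitochondrial genome were added after the data were seen. GC content and length trends were fitted with mgcv 1.9.3, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No deposited column was left out.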

Results

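Messenger RNA was sequenced from A375 cells, an established human melanoma line that carries an activating BRAF mutation, grown with or without recombinant arginine deiminase (ADI). ADI is an enzyme that converts arginine to citrulline and so removes arginine from the medium. The 2 ADI libraries came from cells harvested 48 hours after ADI was added at 250 ng/ml, and the 2 control libraries from cells without it. No harvest time was recorded here for the controls, so a match in time is not known. Total gene counts were 19545694 and 19979467 in the control libraries and 16521311 and 15848802 in the ADI libraries, so that 1 count stood for 0.0501 to 0.0631 CPM, which are counts scaled to a common library total. Genes of the mitochondrial genome held 5.11% and 5.53% of the control counts and 5.19% and 4.39% of the ADI counts. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

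The comparison of ADI with control asked how the transcriptome of A375 cells differed after arginine was withdrawn, in a series about cancers that lack argininosuccinate synthase 1 (ASS1). In ADI-treated cells, genes of the amino acid stress response, MAPK signalling output and inflammation rose, while genes of mitosis, DNA replication, cholesterol synthesis and the interferon response fell. Each of these 7 lists passed camera with the preset correlation, and each had an adjusted p of 0.40 with an estimated correlation. Among 37 tested targets of the stress transcription factor ATF4, 33 rose and 1 fell, and among 40 tested mitotic genes all 40 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The gene for ASS1 itself rose 32.3-fold from a very low level. Of 16962 genes tested, 11899 (70.2%) passed the threshold, 5884 higher and 6015 lower, and 2956 of the higher and 2962 of the lower genes changed at least 2-fold. The quartiles of the log2 fold change over all tested genes lay at -0.70 and 0.68, with a median of -0.011, and the genes that fell held 51.3% of the control counts. Of 12802 protein-coding genes tested, 4421 rose and 5200 fell, or 4686 and 4857 when they alone were scaled and tested. Which direction held more genes depended on the scaling, with 5507 higher and 6365 lower by library totals, 6056 and 5873 by RLE and 6359 and 5566 by upper-quartile scaling.

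Values for single genes are given as mean ± SD of TMM-scaled CPM with n = 2 libraries per group, and log2 fold changes as estimate ± SE. All 87 genes given by the rule set in advance passed the threshold, 45 higher and 42 lower, with a largest edgeR adjusted p of 0.0073. Counts of list members are over all genes tested. For the 35 lists of this report they were the same when adjusted over the list alone except in 5, where both are given. None of the 21 list calls held when camera estimated the correlation between genes from these 4 libraries, and that adjusted p is given beside each.

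ASS1 (ENSG00000130707.18, hg38 chromosome 9, 130444961 to 130501274), which joins citrulline to aspartate in the resynthesis of arginine, rose from 0.274 ± 0.0401 to 9.03 ± 0.533 CPM, a log2 fold change of 5.01 ± 0.251 (edgeR adjusted p = 6.5e-07). Its counts were 6 and 5 in the controls and 152 and 134 in the ADI libraries. ASL (chromosome 7, 66075819 to 66093576), which encodes the next enzyme of that route, fell 1.59-fold from 21.9 ± 0.1504 to 13.8 ± 2.34 CPM (edgeR adjusted p = 0.0018). SLC7A1 (chromosome 13, 29509414 to 29595688), the cationic amino acid transporter that imports arginine, rose 2.97-fold from 221 ± 4.11 to 656 ± 8.10 CPM. ATF4 (chromosome 22, 39519695 to 39522686) rose 3.17-fold from 292 ± 10.3 to 926 ± 55.7 CPM. DDIT3 (chromosome 12, 57516588 to 57521737), which encodes the stress transcription factor CHOP, rose 5.10-fold from 16.8 ± 0.445 to 85.7 ± 7.45 CPM. ASNS (chromosome 7, 97851677 to 97872542), asparagine synthetase, rose 8.02-fold from 126 ± 1.96 to 1013 ± 121 CPM, with a log2 fold change of 3.00 ± 0.0908 (edgeR adjusted p = 5.4e-08).

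**Figure D1:**
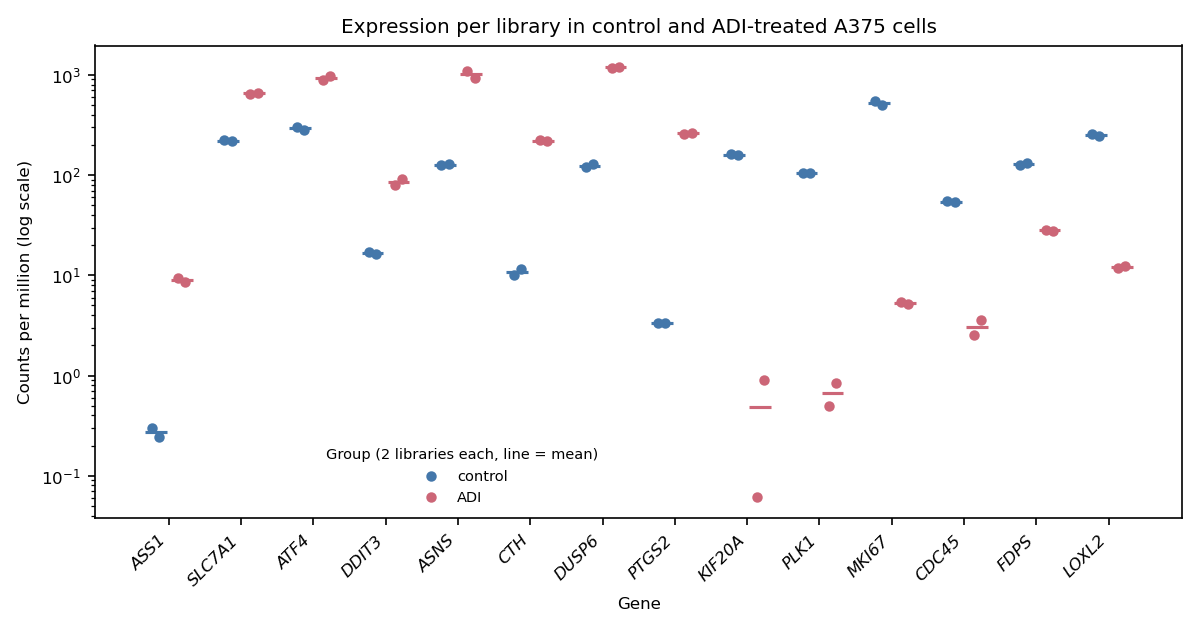
CPM of 14 genes on a log axis in each of the 2 control and 2 ADI libraries, with each point a library and each line the mean of its group. The 8 genes on the left sit higher in both ADI libraries (ASS1 at a mean of 0.274 in controls and 9.03 under ADI) and the 6 on the right sit lower (MKI67 at a mean of 525 and 5.31).

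The ATF4 target list, genes induced through ATF4 when amino acids run short, had a median log2 fold change of 2.35 (camera adjusted p = 5.8e-36, and adjusted p = 0.40 with an estimated correlation). ADM2, a secreted peptide of the calcitonin family, rose 49.9-fold from 2.46 ± 0.201 to 123 ± 33.7 CPM. INHBE, an activin subunit induced by this stress response, had 1 count over both controls and 87 over both ADI libraries. The scaled ratio was 111, with a 95% counting interval of 19.4 to 4423. Of 25 tested amino acid transporters, 17 rose and 7 fell (camera adjusted p = 2.9e-07, and adjusted p = 0.40 with an estimated correlation). SLC38A1, a neutral amino acid transporter, rose 20.96-fold from 24.4 ± 2.48 to 510.5 ± 23.9 CPM, and SLC3A2, the heavy chain shared by several exchangers, rose 10.4-fold from 135 ± 2.62 to 1405 ± 226 CPM. Of these transporters 8 also stood in the ATF4 target list, and the call was lost when genes held by several lists were kept in the first list alone (camera adjusted p = 0.26). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 12 rose and 5 fell (camera adjusted p = 0.029, and adjusted p = 0.45 with an estimated correlation). WARS1, the tryptophan enzyme, rose 3.61-fold from 315 ± 2.61 to 1137 ± 5.50 CPM, whereas QARS1, the glutamine enzyme, fell 4.13-fold from 309 ± 17.5 to 74.9 ± 7.13 CPM. This call was lost without control replicate 1 (camera adjusted p = 0.065) and without control replicate 2 (camera adjusted p = 0.067).

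The arginine, urea cycle and polyamine genes moved both ways, with 8 of 25 higher and 12 lower, and the list as a whole did not pass (camera adjusted p = 0.48, and adjusted p = 0.59 with an estimated correlation). GAMT, which uses an arginine product to make creatine, fell 13.97-fold from 25.7 ± 1.59 to 1.83 ± 0.302 CPM. The cysteine and glutathione genes were also split, with 8 of 22 higher and 8 lower (camera adjusted p = 0.23, and adjusted p = 0.48 with an estimated correlation). CTH, the enzyme that releases cysteine from cystathionine, rose 20.1-fold from 10.9 ± 1.10 to 219.5 ± 4.12 CPM, and CHAC1, which degrades glutathione, rose 9.27-fold from 36.2 ± 0.4798 to 335 ± 77.01 CPM. Mitochondrial aminoacyl-tRNA synthetases showed 4 of 16 higher and 8 lower (camera adjusted p = 0.33, and adjusted p = 0.56 with an estimated correlation). SARS2 was 4.16-fold lower, but only 28.3% of its exonic bases were free of other genes, so its value is uncertain.

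The mitosis list showed the largest shift of the 35 lists, with a median log2 fold change of -4.72 and 40 of 40 tested members lower (camera adjusted p = 2.0e-95, and adjusted p = 0.40 with an estimated correlation). PLK1 (chromosome 16, 23678889 to 23690367), a kinase that drives entry into and passage through mitosis, fell 157-fold from 105 ± 1.62 to 0.667 ± 0.244 CPM (edgeR adjusted p = 9.1e-09). KIF20A (chromosome 5, 138179112 to 138187723), a kinesin of cell division, had 3202 and 3258 counts in the controls and 1 and 14 in the ADI libraries. Its 333-fold fall became 176-fold without ADI replicate 1 and 2282-fold without ADI replicate 2. MKI67, the proliferation marker, fell 98.7-fold from 525 ± 31.7 to 5.31 ± 0.198 CPM, and CENPA, the histone H3 variant of centromeres, fell from 24.2 ± 0.262 to 0.221 ± 0.0381 CPM. Of 40 DNA replication genes, 39 fell and 1 did not pass, with a median of -2.12 (camera adjusted p = 9.0e-24, and adjusted p = 0.40 with an estimated correlation). CDC45, part of the replicative helicase, fell 17.9-fold from 54.4 ± 0.424 to 3.04 ± 0.717 CPM, and E2F8, a cell cycle transcription factor, fell 15.2-fold from 15.998 ± 0.781 to 1.05 ± 0.344 CPM.

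Most transcripts of replication-dependent histone genes lack the poly(A) tail on which these libraries select, so the counts do not give their total level. Only 6 of 35 such genes had enough counts to be tested. Of these 5 rose and 1 did not pass (camera adjusted p = 0.024, and adjusted p = 0.40 with an estimated correlation). A gene low in controls is tested only if it rises, so the filter favours rises. Untested members moved both ways, H2BC9 from 12 and 9 counts to 2 and 2 and H2BC8 from 3 and 4 to 14 and 8. H2AC6 rose 16.7-fold from 1.67 ± 0.557 to 27.9 ± 1.64 CPM, and H2BC5 rose 8.63-fold from 0.945 ± 0.158 to 8.21 ± 1.81 CPM. This call was lost without ADI replicate 1 (camera adjusted p = 0.072), without ADI replicate 2 (camera adjusted p = 0.079) and without a filter on low counts (camera adjusted p = 0.14). Among 25 p53 targets, 15 rose and 6 fell (camera adjusted p = 0.0052, and adjusted p = 0.46 with an estimated correlation). GADD45A, a growth arrest gene, rose 15.1-fold from 20.5 ± 1.64 to 310.4 ± 36.4 CPM, and PMAIP1, which encodes the cell death protein NOXA, rose 9.70-fold from 18.3 ± 0.441 to 178 ± 5.09 CPM. Both are also known to be induced by stress pathways other than p53. Of 16 BCL2 family genes, 9 rose and 5 fell (camera adjusted p = 0.013, and adjusted p = 0.40 with an estimated correlation). HRK, a promoter of cell death, rose 14.5-fold from 1.46 ± 0.00858 to 21.3 ± 1.91 CPM. MCL1, a cell survival gene named after its value was seen, rose 7.03-fold from 280.4 ± 1.84 to 1971 ± 27.3 CPM. The BCL2 family call was lost without a filter on low counts (camera adjusted p = 0.070) and when genes held by several lists were kept in the first list alone (camera adjusted p = 0.088).

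The 8 protein-coding genes with the largest fitted rises, among those with at least 5 CPM in the higher group, all had 0 counts in both control libraries. Such fitted values depend on the prior count, so these genes are not ranked here by size and their rises are known only as lower bounds. KRT6A (chromosome 12, 52487176 to 52493257), a keratin of activated epidermal cells, reached 69.98 ± 4.70 CPM under ADI, at least 469.6-fold higher than a floor of 3 counts per control library. KRT6A has near-identical copies, KRT6B and KRT6C, whose reads could be split with it, and these had 9 and 24 counts and 2 and 11 counts in the ADI libraries. CCND2 (chromosome 12, 4273762 to 4305353), a D-type cyclin, reached 62.9 ± 3.01 CPM, at least 422-fold higher. IL1RL1, the interleukin 33 receptor, reached 28.8 ± 7.93 CPM and RTL1, a retrotransposon-derived imprinted gene, 21.8 ± 4.50 CPM. IRX4, a homeobox gene, had 134 and 289 counts in the ADI libraries. Without a filter on low counts it no longer passed (edgeR adjusted p = 0.19). REG3G, a secreted lectin, reached 12.3 ± 1.19 CPM, GFRA1, a GDNF receptor subunit, 10.6 ± 0.453 CPM and HMX3, a homeobox gene, 9.42 ± 1.94 CPM. Beside KIF20A, PLK1, CENPA and MKI67, the 8 largest fitted falls included MGP, matrix Gla protein, which fell 108-fold from 259 ± 9.15 to 2.40 ± 0.196 CPM. LRRC17 fell from 181 and 239 counts to 1 and 0, a scaled ratio of 330 with a 95% counting interval of 58.9 to 13060. FAM167B fell from 293 and 273 counts to 2 and 0, a scaled ratio of 222 with an interval of 61.3 to 1840. PLEKHS1 fell from 270 and 278 counts to 4 and 0.

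Genes for making ribosomes rose together, with 25 of 32 higher and 2 lower (camera adjusted p = 8.4e-05, and adjusted p = 0.40 with an estimated correlation). MYC, a transcription factor that promotes ribosome production, rose 6.49-fold from 70.8 ± 0.615 to 459.6 ± 93.4 CPM, and RRN3, an initiation factor of RNA polymerase I, rose 3.80-fold from 99.002 ± 2.49 to 376 ± 0.156 CPM. The cytosolic ribosomal proteins themselves did not shift as a list, with 33 of 78 higher and 22 lower (camera adjusted p = 0.32, and adjusted p = 0.73 with an estimated correlation). RPS12 rose 2.18-fold and RPL27 1.99-fold. Of 30 translation factors, 14 rose and 7 fell (camera adjusted p = 0.11, and adjusted p = 0.51 with an estimated correlation). EIF1, which guides start codon choice, rose 5.75-fold from 324 ± 4.68 to 1866 ± 56.7 CPM, and EIF4B, which assists the helicase of initiation, fell 2.62-fold from 619.8 ± 11.3 to 237 ± 19.5 CPM.

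Cytosolic heat shock genes fell, with 11 of 19 lower and 5 higher (camera adjusted p = 0.037, and adjusted p = 0.40 with an estimated correlation). HSP90AA1, an abundant chaperone, fell 2.97-fold from 2108 ± 56.7 to 709.9 ± 11.03 CPM, and CRYAB, a small heat shock protein, fell from 423 and 430 counts to 15 and 7. This call was lost with the stricter filter on low counts (camera adjusted p = 0.10) and without control replicate 1 (camera adjusted p = 0.051). The endoplasmic reticulum list had 8 of 21 members higher and 11 lower, or 8 and 12 when adjusted over the list alone (camera adjusted p = 0.33, and adjusted p = 0.61 with an estimated correlation). Its median of -0.20 and its mean of 0.22 differed in sign. HERPUD1, part of the degradation machinery of that compartment, rose 7.60-fold from 49.2 ± 1.88 to 374 ± 30.5 CPM, and XBP1, a transcription factor of the unfolded protein response, rose 7.58-fold from 103 ± 2.64 to 779.8 ± 40.6 CPM. Of 32 proteasome genes, 18 fell and 7 rose (camera adjusted p = 0.064, and adjusted p = 0.49 with an estimated correlation), with PSMD1 3.07-fold and PSMD2 2.90-fold lower. Lysosome and autophagy genes moved both ways, with 16 of 42 higher and 21 lower, or 16 and 22 when adjusted over the list alone (camera adjusted p = 0.54, and adjusted p = 0.61 with an estimated correlation). MAP1LC3B, a component of autophagosomes, rose 4.73-fold from 114 ± 0.0988 to 539 ± 14.1 CPM, and TFEB, a regulator of lysosome genes, rose 4.59-fold from 1.46 ± 0.219 to 6.76 ± 1.59 CPM.

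Cholesterol synthesis genes fell, with 20 of 23 lower, 1 higher and a median log2 fold change of -1.08 (camera adjusted p = 1.5e-05, and adjusted p = 0.40 with an estimated correlation). FDPS, farnesyl diphosphate synthase, fell 4.62-fold from 129.6 ± 2.82 to 28.03 ± 0.273 CPM. EBP, a sterol isomerase, was 4.39-fold lower, with 42.9% of its exonic bases free of other genes. Fatty acid synthesis genes were split, 4 of 13 higher and 7 lower (camera adjusted p = 0.72, and adjusted p = 0.83 with an estimated correlation). ACSL3, a fatty acid activating enzyme, rose 6.35-fold from 532 ± 6.94 to 3376 ± 181 CPM, and ACLY, which makes cytosolic acetyl-CoA, fell 2.51-fold from 564 ± 15.7 to 224 ± 1.52 CPM. Of 30 hypoxia and glycolysis genes, 19 fell and 8 rose (camera adjusted p = 0.033, and adjusted p = 0.40 with an estimated correlation), and the call was lost with the stricter filter (camera adjusted p = 0.084). HK1, a hexokinase, fell 3.99-fold from 456 ± 19.5 to 114 ± 1.56 CPM, and ALDOC, an aldolase, fell 4.16-fold from 53.7 ± 1.08 to 12.9 ± 2.43 CPM.

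Nuclear genes of the respiratory chain fell, with 31 of 45 lower and 3 higher, or 32 and 3 when adjusted over the list alone (camera adjusted p = 0.0028, and adjusted p = 0.45 with an estimated correlation). UQCRC2, a core subunit of complex III, fell 3.16-fold from 146 ± 4.78 to 45.9 ± 10.9 CPM. ATP5F1D, a subunit of ATP synthase, fell 2.84-fold, but did not pass without a filter on low counts (edgeR adjusted p = 0.092). Of 13 protein genes of the mitochondrial genome, 9 fell and 1 rose (camera adjusted p = 0.21, and adjusted p = 0.75 with an estimated correlation). MT-ATP6 fell 2.24-fold from 4090.3 ± 176 to 1822 ± 264 CPM, and MT-ATP8 fell 2.17-fold from 1045 ± 59.9 to 481 ± 88.9 CPM. Targets of the oxidative stress factor NRF2 fell, with 12 of 22 lower and 5 higher (camera adjusted p = 0.04, and adjusted p = 0.40 with an estimated correlation), and the call was lost with the stricter filter (camera adjusted p = 0.10). ABCC2, an export pump, fell 6.28-fold from 194 ± 4.81 to 30.8 ± 7.16 CPM, and AKR1C2, an aldo-keto reductase, fell from 37 and 32 counts to 7 and 2.

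Interferon-stimulated genes fell, with 20 of 31 lower and 3 higher (camera adjusted p = 0.0068, and adjusted p = 0.40 with an estimated correlation). GBP2, a guanylate-binding protein, fell from 463 and 436 counts to 43 and 14, and IFIT1, which binds viral RNA, from 116 and 155 counts to 6 and 0. The genes of MHC class I antigen presentation were split, with 7 of 21 higher and 12 lower, and the list did not pass (camera adjusted p = 0.53, and adjusted p = 0.63 with an estimated correlation). CALR, a chaperone of the peptide-loading complex, fell 2.57-fold from 1417 ± 17.3 to 552 ± 39.4 CPM, and ERAP2, which trims peptides, fell 4.71-fold from 4.94 ± 0.297 to 1.04 ± 0.0761 CPM. The members that rose included heavy chains and the peptide transporter, named here after their values were seen. HLA-B rose 2.53-fold from 71.6 ± 4.91 to 181 ± 4.15 CPM, HLA-C 1.54-fold, HLA-E 1.94-fold, HLA-F 1.76-fold, TAP1 1.54-fold and TAP2 2.20-fold. HLA genes share near-identical stretches, and HLA-B and HLA-C had 21.9% and 47.9% of their exonic bases free of other genes, so their values are uncertain. HLA-F did not pass without control replicate 2 (edgeR adjusted p = 0.095). The light chain B2M, also named afterwards, fell 1.92-fold from 272 ± 4.98 to 142 ± 11.4 CPM, and the immunoproteasome subunits PSMB8 and PSMB9 fell 1.88-fold and 2.32-fold, the proteasome activator subunit PSME1 2.43-fold and TAPBP, which bridges heavy chains to the transporter, 2.06-fold. PSMB10, another immunoproteasome subunit, went from 50 and 50 counts to 14 and 27 (edgeR adjusted p = 0.026), and did not pass with DESeq2 (adjusted p = 0.14) or without control replicate 1, control replicate 2 or ADI replicate 1 (edgeR adjusted p = 0.080, 0.070 and 0.13). Of 10 MHC class II genes, 3 rose and 5 fell, or 5 and 5 when adjusted over the list alone (camera adjusted p = 0.72, and adjusted p = 0.83 with an estimated correlation). CIITA, the class II transactivator, rose 4.01-fold from 39.4 ± 0.293 to 158 ± 22.9 CPM, while HLA-DMB, a class II peptide exchange factor, fell 4.68-fold from 14.2 ± 0.726 to 3.02 ± 0.624 CPM.

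Genes induced by MAPK signalling, the pathway driven by mutant BRAF in this line, rose, with 18 of 22 higher and 2 lower, or 19 and 2 when adjusted over the list alone (camera adjusted p = 1.9e-09, and adjusted p = 0.40 with an estimated correlation). EGR1, an immediate early transcription factor, rose 20.8-fold from 29.4 ± 1.73 to 611 ± 187 CPM, and DUSP6, a phosphatase of ERK, rose 9.55-fold from 125 ± 6.63 to 1191 ± 11.2 CPM. NF-kB and inflammatory genes rose, with 11 of 18 higher and 2 lower (camera adjusted p = 1.1e-07, and adjusted p = 0.40 with an estimated correlation). PTGS2, which encodes cyclooxygenase-2, rose 77.98-fold from 3.35 ± 0.0256 to 262 ± 4.76 CPM, and the cytokine IL11 rose from 4 and 12 counts to 966 and 952. Melanocyte differentiation genes fell, with 11 of 17 lower and 5 higher (camera adjusted p = 0.01, and adjusted p = 0.43 with an estimated correlation). SLC24A5, a pigment granule exchanger, fell from 27 and 41 counts to 2 and 0, a scaled ratio of 26.7 with a 95% counting interval of 7.12 to 225. OCA2, another pigment gene, instead rose from 0 in both controls to 31 and 20 counts. Markers of dedifferentiated melanoma moved both ways, with 10 of 23 higher and 8 lower (camera adjusted p = 0.57, and adjusted p = 0.64 with an estimated correlation). That list's median of -0.055 and mean of 0.20 differed in sign. NRG1, a growth factor, rose from 1 count over both controls to 113 and 135, a scaled ratio of 316 with a counting interval of 56.1 to 12520. LOXL2, a matrix cross-linking enzyme, fell 20.8-fold from 254 ± 8.14 to 12.2 ± 0.457 CPM.

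**Figure D2:**
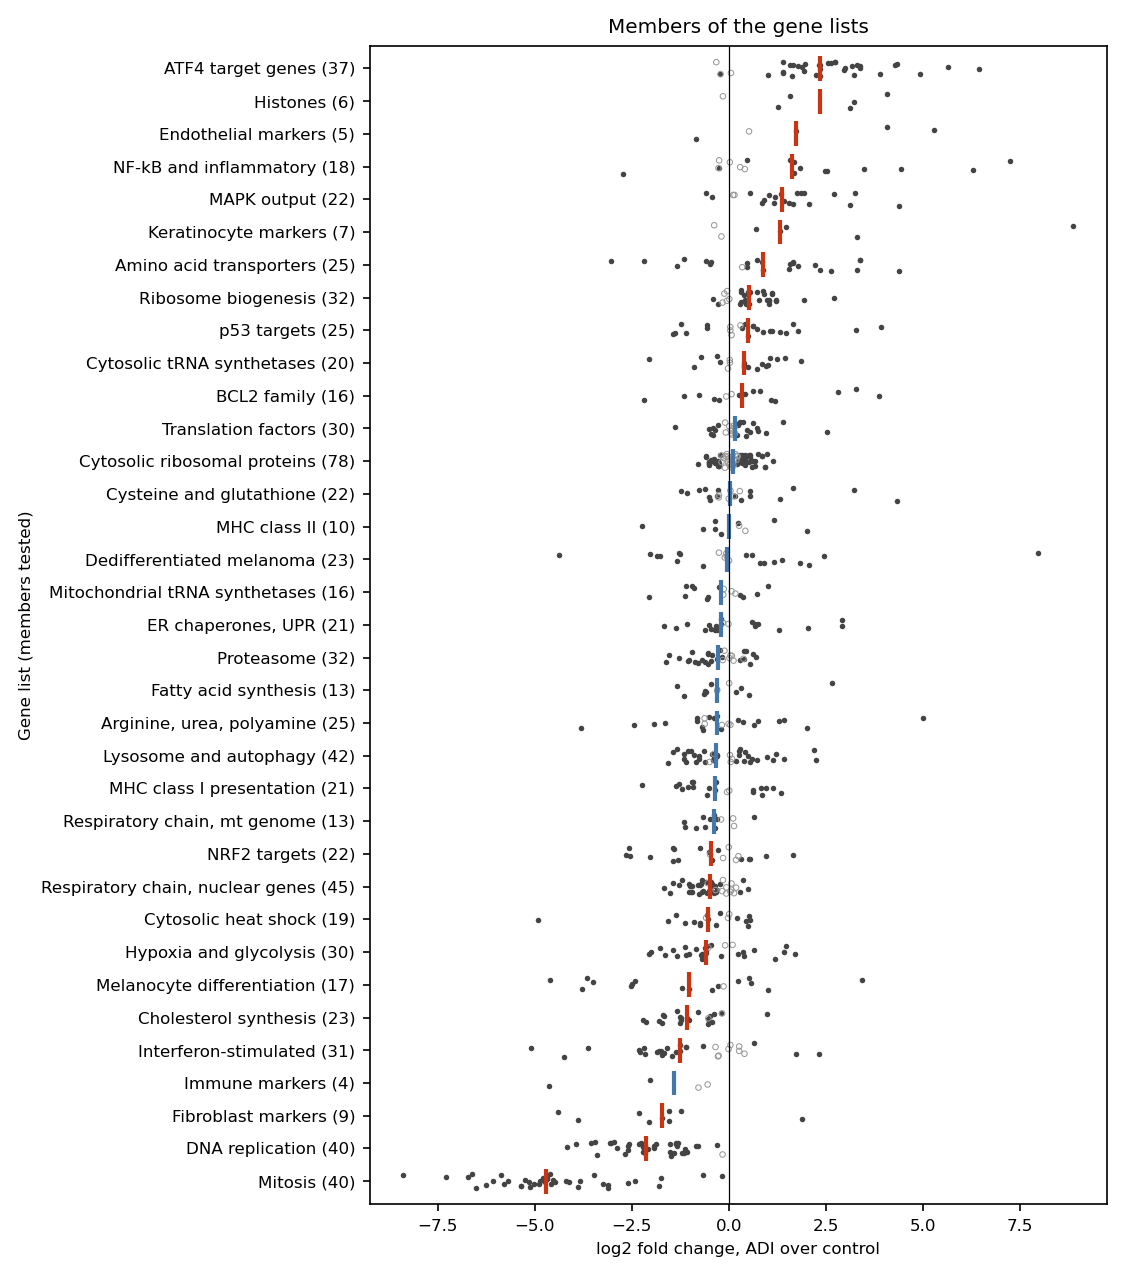
Log2 fold change of ADI over control for each tested member of the 35 gene lists, with filled points for genes past an adjusted p of 0.05, open points for the others and a bar at each list's median, red where the list passed camera with the preset correlation and blue where it did not. Genes with 0 counts in both libraries of a group are drawn at their lower bound, and the medians run from -4.72 for mitosis to 2.35 for ATF4 targets.

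Markers of other cell types, included because a culture can hold other cells, moved in different directions. Of 7 tested keratinocyte markers, 5 rose and 0 fell (camera adjusted p = 0.0052, and adjusted p = 0.40 with an estimated correlation), with KRT6A as above and DSC3, a desmosome gene, at 4 and 1 counts in controls and 22 and 19 under ADI. The epidermal keratin genes KRT5 and KRT14 had 0 counts in both ADI libraries, and 10 of the 17 markers were too low to be tested. Of 9 fibroblast markers, 8 fell and 1 rose (camera adjusted p = 0.04, and adjusted p = 0.44 with an estimated correlation). DCN, decorin, fell from 28 and 31 counts to 0 and 2, a scaled ratio of 23.2 with a counting interval of 6.14 to 196. FAP, a membrane protease, fell from 196 and 221 counts to 15 and 7. The fibroblast call was lost without ADI replicate 1 (camera adjusted p = 0.17) and without ADI replicate 2 (camera adjusted p = 0.12). Of 4 immune markers, 2 fell and 2 did not pass (camera adjusted p = 0.11, and adjusted p = 0.52 with an estimated correlation). FCER1G, an Fc receptor chain, fell from 65 and 69 counts to 2 and 2, and LCP1, an actin-bundling protein, fell 4.07-fold from 28.1 ± 0.194 to 6.88 ± 0.329 CPM. Of 5 endothelial markers, 3 rose and 1 fell (camera adjusted p = 0.016, and adjusted p = 0.40 with an estimated correlation). FLT1, a VEGF receptor, rose 39.03-fold from 10.5 ± 0.576 to 408 ± 29.7 CPM. ESAM, an adhesion molecule, had 10 and 4 counts in controls and 17 and 20 under ADI, and did not pass with DESeq2 (adjusted p = 0.058). Without a filter on low counts the keratinocyte call (camera adjusted p = 0.078) and the endothelial call (camera adjusted p = 0.37) were lost.

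The list calls rest on camera with its preset correlation. Camera with an estimated correlation called none of the 35 lists. The size of the correlation is not the whole reason. Estimates for keratinocyte markers (-0.128), histones (-0.187) and NRF2 targets (-0.0387) lay below the preset 0.01. Yet their unadjusted camera p rose from 0.0016 to 0.083, from 0.011 to 0.12 and from 0.024 to 0.13. When the correlation is estimated, camera judges its statistic on the residual degrees of freedom, here 2, but not when it is preset. This raises p whatever the correlation, and how much of the loss of calls it made up was not tested. Because 70.2% of the tested genes changed, fold changes are relative to the scaling between libraries, and no measure of RNA per cell was used here.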

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

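Of the alternatives, the crossed pairing, the thinned counts, the set without the mitochondrial genome and all tests of added lists and of genes named afterwards were chosen after the data were seen. Across scaling, filter, test and biotype settings, between 9525 genes (stricter filter) and 13100 (no filter) were called, against 11899, and in no setting was a gene called in both fits in opposite directions. The median shift of log2 fold changes under another scaling was at most 0.076. At least 2-fold rises numbered 1827 with the stricter filter, which tested fewer genes (12499), against 2956. Leaving out 1 library shifted log2 fold changes by a median of at most 0.037. In such a fit the lone library is assumed to vary like the other group. The main test likewise uses a spread per gene shared by both groups. The groups did not vary equally, with an SD of the log2 difference between replicates of 0.101 for controls and 0.233 for ADI, so p-values may understate the ADI spread. Replicate numbers are not stated to pair the samples, and same-numbered libraries deviated in opposite directions (r = -0.27 across 9744 genes). With the replicate block 11457 genes were called, and with the crossed pairing 12099. No list call or named gene changed under the block.

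None (0) of the 35 lists passed camera with an estimated correlation. As said above, the size of the correlation was not the whole reason, since camera then also rests on 2 residual degrees of freedom. The share of each was not tested. In counts simulated for this design, camera with an estimated correlation gave adjusted p = 0.034 for 1 list raised 2-fold among 35. There genes were independent of each other and few changed, whereas 70.2% were called in the data. The simulation therefore does not say what removed the calls here. In the data 2 lists, mitosis and ATF4 targets, had an unadjusted p under 0.05, while fry, which tests a list on its own, called 31 lists, 10 of them not called by camera. Across all list settings 326 results stayed on their side of the threshold, 37 lost their call, 21 of these under the estimated correlation, and 17 gained one. The direction of 3 uncalled lists turned, with camera adjusted p = 0.61 for the endoplasmic reticulum list and 0.85 for MHC class II without a filter, and 0.64 for cysteine and glutathione when shared genes were kept in the first list alone. The added list of RNAs without a poly(A) tail also turned without a filter (0.89). The cause of these turns was not tested. For the 10 lists whose call also ended under another setting, the highest adjusted p over all settings was that with the estimated correlation. The lowest, by camera or fry, was 0.0024 for cytosolic synthetases, 9.8e-14 for transporters, 0.0080 for heat shock, 0.0043 for histones, 0.0024 for hypoxia, 0.0049 for NRF2 targets, 0.0045 for the BCL2 family, 0.00037 for keratinocyte, 0.0021 for fibroblast and 0.0071 for endothelial markers. Uncalled lists were gained by camera for the proteasome (0.012 without a filter, 0.040 without ADI replicate 1), translation factors (0.037 without a filter, 0.038 without ADI replicate 2), mitochondrially encoded respiratory genes (0.022 without a filter, 0.0018 without ADI replicate 1) and ribosomal proteins (0.042 without ADI replicate 2). Of the results for genes given by the rule, 1467 kept their call and 3 lost it (IRX4, ATP5F1D and ESAM). Of those for genes named afterwards, 711 kept it and 7 lost it (PSMB10, MT-RNR1 and HLA-F). Genes with a few counts in 1 group set the limit of depth, since leaving out 1 library moved folds by over 1.5 times, as for IFIT1, PLEKHS1, DCN and FAM167B, for which counts are given.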

Other observations

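The genes, the lists of growth factor ligands, activin signalling and cornified envelope genes, and the test of S phase described here were chosen after the calls had been seen, so those lists are not independent evidence. The list of snoRNA host genes followed a rise of such genes already seen in these data, so its tests are not independent evidence either. The lists of decay factors and RNAs without a poly(A) tail were chosen before their own values were seen. For all lists named here, camera p-values were adjusted over these added lists alone, apart from the lists fixed in advance. Their adjusted values are therefore not comparable with those of the lists fixed in advance. By camera with an estimated correlation, unadjusted p was 0.024 for cornified envelope genes, 0.037 for snoRNA hosts and 0.038 for activin signalling. It was 0.016 for mitosis and 0.034 for ATF4 targets.

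INHBA, which encodes the activin A subunit, rose 916-fold from 5.29 ± 0.342 to 4852 ± 262 CPM, and FST, which encodes the activin antagonist follistatin, rose 112-fold from 22.04 ± 1.21 to 2461 ± 55.8 CPM. IGFBP3, which binds insulin-like growth factors, rose 57.9-fold from 40.9 ± 0.459 to 2368 ± 190.1 CPM. Of 17 activin and TGF-beta pathway genes, 9 rose and 4 fell (camera adjusted p = 8.5e-06, and adjusted p = 0.077 with an estimated correlation), with SKIL 3.32-fold higher and TGFB2 and TGFB3 2.09-fold and 2.36-fold lower. Without a filter on low counts that call was lost (camera adjusted p = 0.056). Of 5 tested ligands of the EGF receptor family, 4 rose and 1 fell (camera adjusted p = 0.003, and adjusted p = 0.13 with an estimated correlation). AREG, amphiregulin, went from 2 and 0 counts in controls to 1055 and 1270, a scaled ratio of 1480 with a 95% counting interval of 409 to 12230. EREG, epiregulin, went from 0 and 1 to 73 and 100, a scaled ratio of 220 with an interval of 39 to 8747. HBEGF rose 3.37-fold and TGFA 1.52-fold, while EGF itself fell from 255 and 260 counts to 50 and 23. Of 25 genes of the cornified envelope, the outer layer of skin cells, 16 had too few counts to be tested, SPRR1A, SPRR1B, SPRR3, TGM3, S100A7, S100A8 and S100A9 with 0 in all 4 libraries, TGM1 with 5 and 10 in controls and 8 and 8 under ADI, and CNFN with 8 and 4 and then 0 and 2. Of the 9 tested, 8 rose, but a gene at 0 in controls is tested only if it rises, so the filter favours rises (camera adjusted p = 4.5e-12, and adjusted p = 0.077 with an estimated correlation, median log2 fold change 4.46 with genes at 0 in controls set to their bounds). SPRR2D rose 92.6-fold from 6.30 ± 0.518 to 584 ± 65.5 CPM, DSP 117-fold from 3.06 ± 0.0905 to 358 ± 29.8 CPM and KRT79 from 1 and 4 counts to 302 and 333. SPRR2A and KRT16, at 0 in controls, were at least 29.8-fold and 20.2-fold higher. Outside that list, the keratinocyte markers KRT10 and PERP, already expressed in controls, rose 2.79-fold and 1.62-fold.

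More genes were switched on than off. With 0 counts in both controls and at least 20 in both ADI libraries there were 51 genes, 37 of them protein-coding, against 6 genes, 3 of them protein-coding, with the reverse. After all libraries were thinned to the smallest total, the numbers were 61 and 4. In the mitochondrial genome, the large ribosomal RNA MT-RNR2 rose 3.92-fold from 2027 ± 105 to 7949 ± 821 CPM and MT-ND1, which lies next to it, rose 1.58-fold, while 9 of the 13 protein genes fell. The small ribosomal RNA MT-RNR1 rose only 1.24-fold from 651 ± 32.95 to 808 ± 16.02 CPM, and did not pass when tested against a 1.2-fold change (edgeR adjusted p = 0.13) or without control replicate 1 (edgeR adjusted p = 0.084). The 2 ribosomal RNAs of that genome together held 0.262% and 0.283% of control counts and 0.914% and 0.798% of ADI counts. Among interferon-stimulated genes ISG20 went against the list and rose 4.96-fold from 27.8 ± 0.293 to 138 ± 20.3 CPM. Host genes of small nucleolar RNAs, of which SNHG32 alone is annotated as protein-coding, were higher, with 18 of 26 tested up and 3 down (camera adjusted p = 2.7e-06, and adjusted p = 0.077 with an estimated correlation), as in GAS5 (5.60-fold higher, 212 ± 4.94 to 1186 ± 175 CPM), SNHG1 (5.42-fold), SNHG32 (5.38-fold), SNHG15 (4.91-fold) and ZFAS1 (4.28-fold), while SNHG16 fell 1.49-fold and SNHG6 1.93-fold. SNHG25 fell from 59 and 70 counts to 5 and 14, 5.28-fold, or 3.52-fold without ADI replicate 1 and 9.89-fold without ADI replicate 2. SNHG6 and SNHG25 overlap other genes (19.2% and 47.4% of exonic bases free), so their values are uncertain.

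Of 7 tested keratinocyte markers 5 rose and 0 fell (camera adjusted p = 0.0052, and adjusted p = 0.40 with an estimated correlation; lost without a filter on low counts, camera adjusted p = 0.078), and 8 of the 9 cornified envelope genes with enough counts to be tested rose, while 16 had too few, a filter that favours rises in genes at 0 in controls. KRT5 and KRT14, among the most abundant keratinocyte transcripts, had 0 counts in the ADI libraries, at most 0.00279 of the KRT6A count when each is set to 3 counts. If both genes could be counted, this argues against keratinocytes mixed into the ADI cultures. Their share of free bases is not given here, and genes such as EEF1G and EIF4A1 had 0 counts in all 4 libraries. Of the 17 markers, 4 had at least 1 CPM in the controls already. An epidermal program switched on by the treatment may be the source, a hypothesis that was not tested here, and no other biological explanation was tested.

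Counts from poly(A) libraries do not give the total level of replication-dependent histone transcripts. Only 6 of 35 histone genes had enough counts to be tested, a filter that favours rises in genes low in controls. Of these 6 histone genes 5 rose, while 39 of 40 DNA replication genes fell. The histone call (camera adjusted p = 0.024, and adjusted p = 0.40 with an estimated correlation) was lost without ADI replicate 1, ADI replicate 2 or a filter on low counts (camera adjusted p = 0.072, 0.079 and 0.14). A larger share of cells in S phase would raise the replication genes, whose median log2 fold change was -2.12, which speaks against it. That fall was known before the comparison was set up, so it is no independent test, and the share of cells in S phase was not measured. More RNA without a poly(A) tail in the ADI libraries could also raise histone transcripts. The 4 tested RNAs of that kind had a median of 0.258, below the 0.5 set in advance as evidence against it, but they ran from 0.025 (RN7SL1) to 2.2 (SNORD3A), so these few genes leave this open.

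The snoRNA host genes were higher in the ADI libraries, with a median log2 fold change of 0.98, and 0.89 in the 25 that are not protein-coding. Of 10000 random lists matched on expression alone 0 had a median as high, and the highest had 0.74. Because the host list followed a rise already seen, this is not independent support for that rise. A smooth trend with gene length and GC content is argued against as the whole cause, since it explained 0.333% of the deviance, was at most 0.26 at any host, moved 21.7% of tested genes by over 0.1 and left a median of 1.02. The other 2300 long noncoding RNA genes tested also leaned higher, with 848 higher and 476 lower, but had a median of only 0.262. A general rise of such genes is thus argued against as the whole cause, not as a part of it. Slower nonsense-mediated decay, which degrades several of these transcripts, may contribute, but 7 decay factors known to limit their own transcripts had a median of 0.237 (camera adjusted p = 0.57), with 4 higher and 1 lower, or 4 and 2 when adjusted over the list alone, so this stays open.

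A further hypothesis was that transcripts rich in arginine codons fell more under arginine withdrawal. Across 12761 protein-coding genes, which are not independent replicates, the partial Spearman correlation of log2 fold change with the arginine codon share, given coding GC content and length, was -0.00894. The values argue against a relation of the size set in advance (-0.2 or lower), and steady-state RNA levels say nothing of translation at those codons.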
